A study of Rattus norvegicus with 12 samples.

How the data were processed

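The deposited values were log2 intensities made by RMA, per the submitters' processing notes, which corrects background, normalizes arrays by quantiles and summarises the probes of each probe set; its version and the genome build are not given in the sources used here, and no positions are printed. The table held 29656 probe sets on 12 arrays with 0 missing values, and the array medians lay between 7.07 and 7.16. No further normalization was applied. Of the probe sets, 18511 had exactly 1 gene symbol, 575 had several and 10570 had none here. A gene was represented by the probe set with the highest mean over all 12 arrays, which mattered for 291 genes with more than 1 probe set and left 18166 genes. No dim genes were left out.

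Each gene was fitted in limma 3.58.1 (R 4.3.3) with group and heart as terms over all 12 arrays, which leaves 6 residual degrees of freedom, since per the labels the treatments were applied to cultures of the same heart. Moderated two-sided tests (eBayes) were adjusted by Benjamini-Hochberg over all genes of a comparison, and genes with an adjusted p under 0.05 were called. Differences are on the log2 scale with the moderated standard error, and the number of hearts with that sign is the number of the 4 within-heart differences that have it. The difference of the 2 steps is (non-p-MyoFb minus p-MyoFb) minus (p-MyoFb minus Fb).

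A total of 29 gene lists, 23 of pathways and 6 of markers of other cell types, were tested with camera at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. Camera with a correlation estimated for each list and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were run beside it. Members of a list were also counted with the limma p adjusted over the list alone. The lists, the tests, the threshold, the alternatives, except those said to have been added later, and the rule for named genes were chosen before the data were examined.

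The rule named 9 common genes of myofibroblasts and dividing cells whatever their result (7 of them were analysed here), the 6 genes that rose most and the 6 that fell most among called genes with the same sign in all 4 hearts, and from each list up to 3 called members with the largest difference or, where none was called, the member with the smallest p. For the difference of the steps it named 5 genes of each sign. Symbols of predicted genes, microRNAs and receptor families were passed over in the ranking. The text names a part of the genes that the lists gave, and other members in passing.

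The procedure was tried on simulated arrays of the same design, with changes of known size in 50 genes each. The simulated errors were independent between genes and had the same spread on all arrays, and each change was the same in every heart. A single set was drawn per comparison, so the shares below hold for such sets and may differ for the measured arrays. At a log2 change of 1 it recovered 92% of them for p-MyoFb against Fb, 84% for non-p-MyoFb against p-MyoFb, 94% for non-p-MyoFb against Fb and 64% for the difference of the steps, with 2.63% to 5.29% of the calls false.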

Results

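Gene expression was measured on 12 Affymetrix Rat Gene 2.0 ST arrays, 1 for each culture of left ventricular cardiac fibroblasts from male Wistar rats. Cells of 4 hearts were each cultured in 3 ways, so every group held 4 arrays and every heart gave 1 array to each group. The hearts are called A, B, C and D here, and their p-MyoFb arrays carry the titles 1-RC-284, 7-RC-314, 10-RC-317 and 4-RC-401 in that order. Fibroblasts (Fb) were kept for 4 days with SD-208 at 3 µmol/L, an inhibitor of the kinase of TGF-β receptor I. Proliferating myofibroblasts (p-MyoFb) arose without added drug or cytokine in standard medium with 10% serum over 4 days. Non-proliferating myofibroblasts (non-p-MyoFb) received 400 pmol/L of TGF-β1 for 6 days, so in that group the cytokine came together with a longer culture. Expression of 18166 genes was compared as log2 intensities. The number of arrays limits the precision of every value.

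The groups separated along the first principal component, which held 51.2% of the variance. Arrays of Fb lay between 22.8 and 51.7 on it, those of p-MyoFb between -11.3 and -6.83, and those of non-p-MyoFb between -32.2 and -27.0. Pearson's correlation across genes between arrays of the same group ran from 0.977 to 0.994, and genes are not independent replicates. The non-p-MyoFb array of heart C has the title 13-NT-317, with another letter code than the other arrays of its group, and it lay within their range on the first component. Deviations from the group means correlated across genes with a mean of 0.24 over the 12 pairs of arrays of the same heart, and of -0.08 between arrays of other hearts and other groups. Deviations of a group cancel over its hearts, so the second of these means follows largely from the first. Heart was kept as a replicate block in every comparison, as planned before the data were examined.

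The comparison of p-MyoFb with Fb asked what differed between cells left to become myofibroblasts and cells in which the TGF-β receptor was blocked. Of 30 listed collagens and matrix proteins 15 rose, with a median difference of 0.54 over the list. Postn (probe set 17738503), which encodes the matricellular protein periostin, rose from 9.52 ± 0.57 to 13.08 ± 0.31 (SD, n = 4). Its difference was 3.56 ± 0.17 (log2, SE; 11.8-fold), higher in 4 of 4 hearts. Col11a1 (17742074), a fibrillar collagen chain, rose by 3.64 ± 0.19, Itga11, a collagen-binding integrin, by 3.57 ± 0.37, and Pmepa1, a TGF-β target that restrains SMAD signalling, by 3.53 ± 0.15. The largest fall was that of Tspan8 (17828240), a tetraspanin, at -4.32 ± 0.50. Pla2g2a, a secreted phospholipase, fell by 3.91 ± 0.28, and Fmod, the collagen-binding proteoglycan fibromodulin, fell by 3.87 ± 0.43. Each of these changes was seen in 4 of 4 hearts.

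Adjusted p was 2.70e-05 for Postn, 3.63e-05 for Col11a1, 7.04e-04 for Itga11 and 2.02e-05 for Pmepa1 (limma, Benjamini-Hochberg). It was 0.00109 for Tspan8, 1.31e-04 for Pla2g2a and 9.28e-04 for Fmod. Gldn rose by 3.85 ± 0.27 (adjusted p = 1.31e-04) and Cmklr1, a receptor for chemerin, by 3.58 ± 0.35 (adjusted p = 5.49e-04), each in 4 of 4 hearts. Dpp4, a membrane peptidase, fell by 3.71 ± 0.69 in 4 of 4 hearts (adjusted p = 0.00944), and its call ended without heart C (adjusted p = 0.0852). Pkhd1l1 fell by 3.57 ± 0.74 in 4 of 4 hearts (adjusted p = 0.0153). Its adjusted p was 0.0749, 0.0710 and 0.0686 without heart B, C or D, 0.0666 without the p-MyoFb array of heart D and 0.0558 without the Fb array of heart C. Cyp2e1, a cytochrome P450, fell by 3.43 ± 0.66 in 4 of 4 hearts (adjusted p = 0.0109). Its adjusted p was 0.0574, 0.0750 and 0.0807 without heart B, C or D and 0.0504 without the p-MyoFb array of heart D. Dpp4 and Cyp2e1 averaged 5.98 and 5.83 in p-MyoFb, near the leukocyte markers Ms4a1 (5.52) and Ptprc (5.70). Other probe sets read lower there, such as that of Fabp7 at 4.78. Whether background limits the falls of Dpp4 and Cyp2e1 therefore cannot be told from these levels.

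Among common myofibroblast genes, Tagln, an actin-binding protein of smooth muscle, rose by 1.79 ± 0.45 (adjusted p = 0.0335) and Col1a1 by 0.41 ± 0.10 (adjusted p = 0.0329), each in 4 of 4 hearts. Both calls ended when single arrays were left out and with only the 8 arrays of the 2 groups (adjusted p = 0.0837 and 0.0761). The call of Tagln ended without heart B (adjusted p = 0.113) or C (0.129) and without any 1 of 8 arrays (up to 0.122), namely all p-MyoFb arrays, the Fb and the non-p-MyoFb arrays of hearts B and C. It also ended with no replicate block (adjusted p = 0.0521). The call of Col1a1 ended without heart B (0.126), C (0.185) or D (0.133) and without any 1 of 8 arrays (0.0507 to 0.112), namely the p-MyoFb and Fb arrays of hearts B, C and D and the non-p-MyoFb arrays of hearts C and D. Col3a1 differed by 0.51 ± 0.16 (adjusted p = 0.0649, higher in 4 of 4 hearts) and passed without the Fb array of heart A (adjusted p = 0.0322). Fn1, which encodes fibronectin, differed by 0.02 ± 0.06 (adjusted p = 0.857, higher in 3 of 4 hearts). Fn1 lay between 13.76 and 13.95 on every array and Col1a1 between 13.07 and 13.92, while the highest values of the arrays were 14.16 to 14.24, a range in which arrays compress differences. Acta2 was not analysed here.

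**Figure D1:**
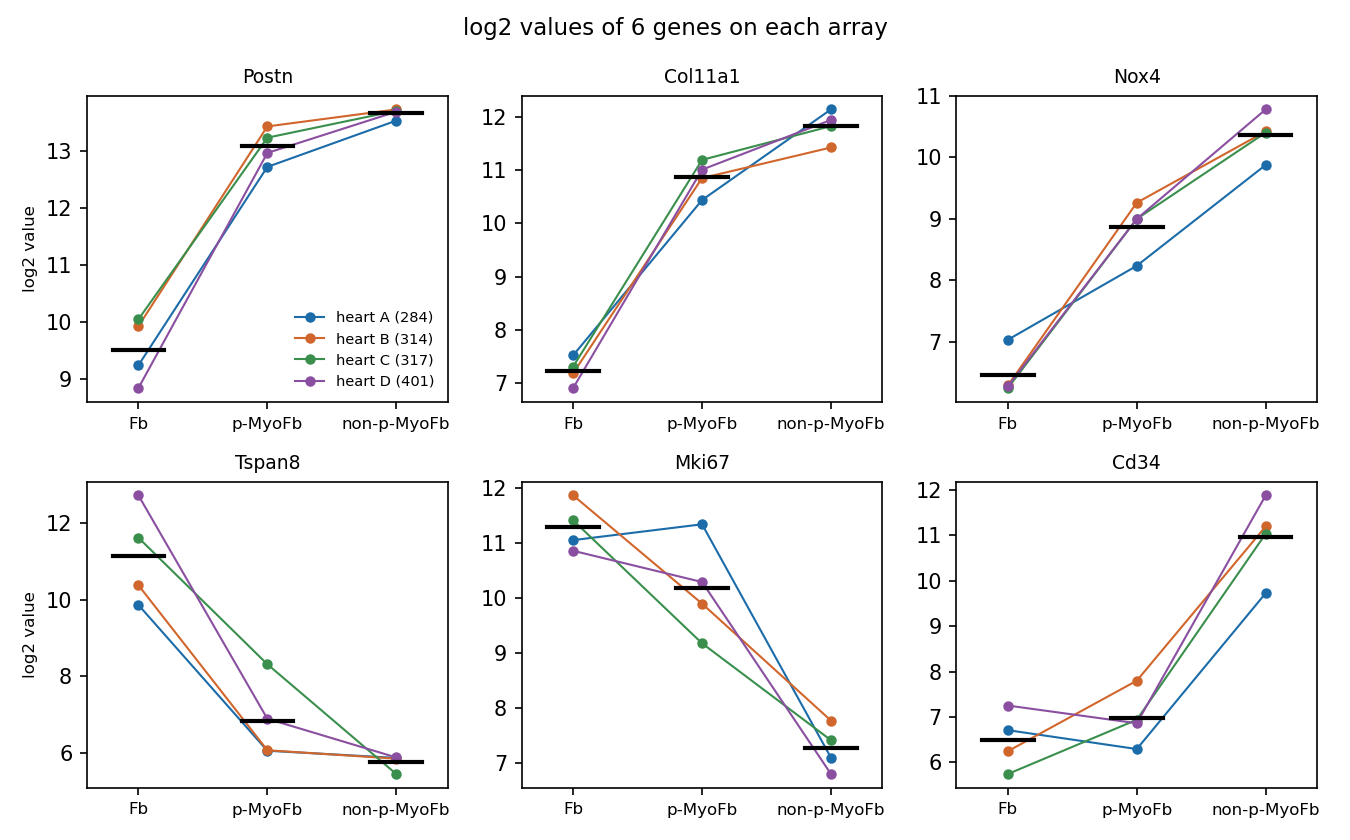
Log2 values (vertical axes) of 6 genes on each of the 12 arrays, by group along the horizontal axis, with the arrays of each heart joined by a coloured line and black bars for the group means. Postn rose in all 4 hearts from Fb to p-MyoFb, and Cd34 lay between 5.74 and 7.80 in Fb and p-MyoFb and between 9.73 and 11.9 in non-p-MyoFb.

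Of 30 measured collagens and matrix proteins, 15 rose in p-MyoFb and 0 fell, or 18 and 1 adjusted over the list alone, and 19 were higher and 1 lower at an unadjusted p under 0.05 in limma. Besides Postn and Col11a1 they included Mfap4, a microfibril-associated protein, up by 3.26 ± 0.15 in 4 of 4 hearts (adjusted p = 2.70e-05). The list rose in camera (mean 0.86, adjusted p = 5.44e-08, higher in 4 of 4 hearts; adjusted p = 0.300 with an estimated correlation). Of 27 contractile and smooth muscle genes, 12 rose and 1 fell, or 15 and 2 adjusted over the list alone. That list rose (mean 0.61, adjusted p = 2.37e-05, higher in 4 of 4 hearts; adjusted p = 0.340 with an estimated correlation). Of 19 genes of collagen processing and crosslinking, 7 rose and 1 fell, or 8 and 1 adjusted over the list alone, among them the lysyl oxidase Loxl2 (1.12 ± 0.15) and the lysyl hydroxylase Plod2 (0.69 ± 0.09). The processing list rose too (mean 0.30, adjusted p = 0.00466, higher in 4 of 4 hearts; adjusted p = 0.231 with an estimated correlation).

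The TGF-β pathway and its targets moved both ways. Of 26 measured members, 13 rose and 3 fell, or 15 and 4 adjusted over the list alone. The list as a whole rose (mean 0.40, adjusted p = 0.00193, higher in 4 of 4 hearts; adjusted p = 0.340 with an estimated correlation). Nox4, an NADPH oxidase, rose by 2.41 ± 0.27 and Tgfbi, a secreted matrix protein, fell by 2.72 ± 0.30, each in 4 of 4 hearts (adjusted p = 9.28e-04 for both). Of 28 integrins and adhesion genes, 10 rose and 2 fell, or 12 and 2 adjusted over the list alone, with Ncam1 up by 2.59 ± 0.19 and Itga3 at -2.51 ± 0.18. The integrin list rose (mean 0.37, adjusted p = 0.00503, higher in 4 of 4 hearts; adjusted p = 0.340 with an estimated correlation). Of 27 genes of the unfolded protein response and the secretory pathway, 8 rose and 1 fell, or 9 and 2 adjusted over the list alone. Among them Creb3l2, a transcription factor of the secretory pathway, rose by 0.95 ± 0.11 and Chac1, an enzyme that degrades glutathione, by 1.30 ± 0.15, each in 4 of 4 hearts. This list rose as well (mean 0.22, adjusted p = 0.00921, higher in 4 of 4 hearts; adjusted p = 0.340 with an estimated correlation).

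Of 27 interferon response genes, 10 fell and 1 rose, or 12 and 1 adjusted over the list alone. Ifi44l fell by 1.45 ± 0.22 and Gbp2, a guanylate-binding protein, fell by 1.42 ± 0.18, each in 4 of 4 hearts. The interferon list fell (mean -0.39, adjusted p = 5.44e-08, lower in 4 of 4 hearts; adjusted p = 0.164 with an estimated correlation). Of 16 complement genes, 6 fell and 0 rose, or 9 and 1 both adjusted over the list alone and at an unadjusted p under 0.05 in limma. C6, a part of the membrane attack complex, fell by 2.68 ± 0.31 and the protease gene C1s fell by 2.31 ± 0.26, each in 4 of 4 hearts. The complement list fell (mean -0.79, adjusted p = 0.00144, lower in 4 of 4 hearts; adjusted p = 0.164 with an estimated correlation).

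The genes of cell division did not move alike in the 4 hearts. The mean of 27 mitosis genes differed by 0.40 in heart A, -1.73 in heart B, -1.76 in heart C and -0.27 in heart D. None of the 27 passed the threshold in limma (0 higher and 0 lower, also adjusted over the list alone; 0 higher and 19 lower at an unadjusted p under 0.05). Camera called the mitosis list lower (mean -0.84, adjusted p = 5.44e-08, lower in 3 of 4 hearts; adjusted p = 0.489 with an estimated correlation), and fry did not (adjusted p = 0.140). Mki67 (17637913), the Ki-67 antigen of dividing cells, differed by -1.12 ± 0.39 (adjusted p = 0.0991, lower in 3 of 4 hearts), and Ccnb1, cyclin B1, by -1.01 ± 0.44 (adjusted p = 0.178, lower in 3 of 4 hearts). Without heart A both passed, Mki67 at -1.59 (adjusted p = 0.0205) and Ccnb1 at -1.51 (adjusted p = 0.0472), as they did without its p-MyoFb array alone (adjusted p = 0.0163 and 0.0376). Of 26 DNA replication genes, 0 passed the threshold in limma (0 adjusted over the list alone; 0 higher and 7 lower at an unadjusted p under 0.05). Camera called that list lower (mean -0.33, adjusted p = 8.26e-05, lower in 3 of 4 hearts; adjusted p = 0.573 with an estimated correlation), and fry did not (adjusted p = 0.273). The DNA replication call ended without heart B (adjusted p = 0.0651).

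**Figure D2:**
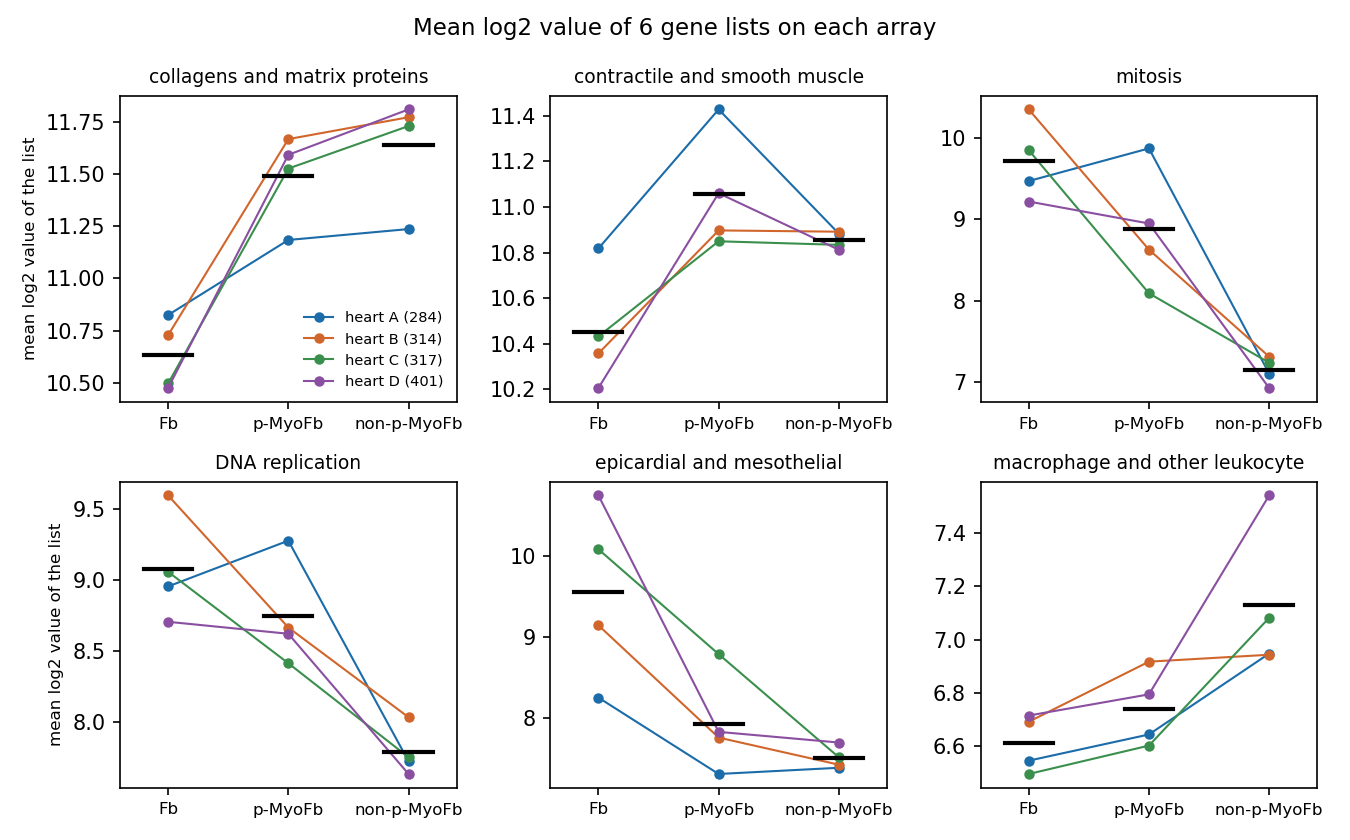
Mean log2 value (vertical axes) of 6 gene lists on each of the 12 arrays, by group along the horizontal axis, with the arrays of each heart joined by a coloured line and black bars for the group means. The mitosis list averaged 9.73 in Fb, 8.89 in p-MyoFb and 7.14 in non-p-MyoFb, and the epicardial and mesothelial list 9.56, 7.92 and 7.51.

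Of 14 epicardial and mesothelial markers, 9 fell in p-MyoFb and 0 rose, or 12 and 0 both adjusted over the list alone and at an unadjusted p under 0.05 in limma. Upk3b, a uroplakin of the mesothelium, fell by 3.22 ± 0.47 in 4 of 4 hearts (adjusted p = 0.00327). The list fell (mean -1.64, adjusted p = 1.08e-07, lower in 4 of 4 hearts; adjusted p = 0.340 with an estimated correlation), with means from -0.94 in heart A to -2.92 in heart D. Of 14 markers of pericytes and vascular smooth muscle, 5 rose and 0 fell, also adjusted over the list alone, with 7 higher and 1 lower at an unadjusted p under 0.05 in limma, and 5 of the 14 are members of other lists too. That list rose (mean 0.54, adjusted p = 0.0267, higher in 4 of 4 hearts; adjusted p = 0.360 with an estimated correlation), and the call ended without heart C (adjusted p = 0.0542) and with dim genes left out (0.0600). The cardiomyocyte, endothelial, leukocyte and Schwann cell lists did not shift in camera, with mean differences of -0.11, 0.09, 0.13 and -0.06 and adjusted p of 0.982, 0.475, 0.503 and 0.398. Fry called the endothelial list (adjusted p = 0.0304) and none of the other 3.

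In all, 1226 genes were higher and 1075 lower in p-MyoFb than in Fb, or 12.7% of those tested (limma, adjusted p under 0.05). Of these, 199 and 270 differed at least 2-fold, and 2271 of the 2301 had the same sign in all 4 hearts. Of the 29 lists, 14 shifted in camera and 12 in fry, and 0 shifted in camera with an estimated correlation, where 4 had an unadjusted p under 0.05. The numbers higher and lower were 654 and 575 without heart B, 357 and 379 without heart C and 424 and 438 without heart D. They were 539 and 497 without the p-MyoFb array of heart D, 609 and 583 without that of heart C, 608 and 573 without the Fb array of heart C and 723 and 690 without that of heart D, and 744 were higher without the Fb array of heart B. With the mean of the epicardial and mesothelial list as a covariate, added after seeing the data, 49 genes were higher and 36 lower. The median rise of the called genes then went from 0.49 to 0.36, their median fall from -0.61 to -0.40 and their median standard error from 0.104 to 0.182, so calls ended because differences shrank and the error grew.

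The comparison of non-p-MyoFb with p-MyoFb asked what TGF-β1 over 6 days added to the state reached in standard medium. Mki67 fell from 10.17 ± 0.90 to 7.27 ± 0.42 (SD, n = 4), a difference of -2.90 ± 0.39 (7.46-fold), and Rrm2, a subunit of ribonucleotide reductase, fell by 3.06 ± 0.41, each in 4 of 4 hearts. Of 27 mitosis genes, 11 fell and 0 rose, or 26 and 0 both adjusted over the list alone and at an unadjusted p under 0.05 in limma. Of 26 DNA replication genes, 11 fell and 0 rose, or 24 and 0 by the same counts. Cd34 (probe set 17683339), a sialomucin of progenitor and some stromal cells, rose from 6.97 ± 0.62 to 10.96 ± 0.90 (SD, n = 4), a difference of 3.99 ± 0.39 (15.9-fold) in 4 of 4 hearts.

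Adjusted p was 0.0267 for Mki67 and Rrm2 and 0.00940 for Cd34 (limma, Benjamini-Hochberg). Sgo2, a protector of centromere cohesion, fell by 3.19 ± 0.44 (adjusted p = 0.0267) and Depdc1 fell by 2.78 ± 0.44 (adjusted p = 0.0343), each in 4 of 4 hearts. Ccna2, cyclin A2, fell by 2.55 ± 0.36 (adjusted p = 0.0267) and Top2a, a topoisomerase, fell by 2.48 ± 0.36 (adjusted p = 0.0293), again in 4 of 4 hearts. Ccnb1 differed by -2.21 ± 0.44 in 4 of 4 hearts (adjusted p = 0.0511) and passed with no replicate block (adjusted p = 0.0369). The mitosis list fell (mean -1.74, adjusted p = 3.32e-26, lower in 4 of 4 hearts; adjusted p = 0.245 with an estimated correlation), with means from -0.86 in heart C to -2.77 in heart A. The DNA replication list fell (mean -0.96, adjusted p = 3.01e-22, lower in 4 of 4 hearts; adjusted p = 0.245 with an estimated correlation).

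After Cd34, the rule named Car3, a carbonic anhydrase, up by 2.39 ± 0.36 (adjusted p = 0.0343), and the cytokine gene Il33, up by 2.00 ± 0.32 (adjusted p = 0.0343), each in 4 of 4 hearts. C1ql3 rose by 1.94 ± 0.19 (adjusted p = 0.00940), Fibin by 1.87 ± 0.35 (adjusted p = 0.0442) and the semaphorin gene Sema7a by 1.82 ± 0.15 (adjusted p = 0.00688), all in 4 of 4 hearts. With no replicate block the calls of Il33 and Fibin ended (adjusted p = 0.192 and 0.0563). That of Il33 also ended with heart as a random effect (0.0982), and that of Fibin with only the 8 arrays of the 2 groups (0.0524) or a trended and robust prior (0.0556). Of 21 CDK inhibitors and senescence genes, 2 rose and 0 fell, or 6 and 3 adjusted over the list alone, with 9 higher and 3 lower at an unadjusted p under 0.05 in limma. Cdkn2b, an inhibitor of CDK4 and CDK6, rose by 1.42 ± 0.20 (adjusted p = 0.0267) and the stress gene Gadd45b by 0.78 ± 0.14 (adjusted p = 0.0407; 0.0557 with only the 8 arrays), both in 4 of 4 hearts. The senescence list rose (mean 0.25, adjusted p = 0.0103, higher in 3 of 4 hearts; adjusted p = 0.363 with an estimated correlation) and not in fry (0.0874). Its call ended without heart A (adjusted p = 0.102) or the non-p-MyoFb array of heart A (0.0573).

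Of the 30 listed collagens and matrix proteins, 0 passed in limma (1 higher adjusted over the list alone; 5 higher and 0 lower at an unadjusted p under 0.05). Postn differed by 0.57 ± 0.17 (adjusted p = 0.144, higher in 4 of 4 hearts) and Col1a1 by 0.04 ± 0.10 (adjusted p = 0.900, higher in 3 of 4 hearts). In non-p-MyoFb Postn read 13.53 to 13.72 and Col1a1 13.70 to 13.92, a range in which arrays compress differences. Col11a1 differed by 0.96 ± 0.19 in 4 of 4 hearts (adjusted p = 0.0521) and passed with no replicate block (adjusted p = 0.0420). The collagen list rose in camera (mean 0.14, adjusted p = 0.0237, higher in 4 of 4 hearts; adjusted p = 0.571 with an estimated correlation) and not in fry (0.443). That call ended without heart C (adjusted p = 0.0692), the p-MyoFb array of heart A (0.117) or the non-p-MyoFb array of heart B (0.0649), C (0.155) or D (0.0628). Nox4 rose further, 2.82-fold in 4 of 4 hearts (adjusted p = 0.0412; 0.0512 with a trended and robust prior), as the 1 member of 26 of the TGF-β list past the threshold, with 4 higher and 1 lower adjusted over the list alone.

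Of 27 contractile and smooth muscle genes, 0 passed in limma (0 adjusted over the list alone; 0 higher and 6 lower at an unadjusted p under 0.05), and Tagln differed by -0.14 ± 0.45 (adjusted p = 0.918, lower in 3 of 4 hearts). The contractile list fell in camera (mean -0.20, adjusted p = 0.0103, lower in 4 of 4 hearts; adjusted p = 0.462 with an estimated correlation) and not in fry (0.219). The call ended without heart A (adjusted p = 0.144), its p-MyoFb array (0.0789) or its non-p-MyoFb array (0.113), and with dim genes left out (0.0620).

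Of 19 leukocyte markers, 0 passed in limma (7 higher adjusted over the list alone; 10 higher and 0 lower at an unadjusted p under 0.05). The leukocyte list rose in camera (mean 0.39, adjusted p = 4.74e-05, higher in 4 of 4 hearts; adjusted p = 0.346 with an estimated correlation) and not in fry (0.0909), with means from 0.03 in heart B to 0.75 in heart D. Of 11 Schwann cell markers, 0 passed in limma (0 adjusted over the list alone; 2 higher and 0 lower at an unadjusted p under 0.05). The Schwann cell list rose (mean 0.20, adjusted p = 0.0103, higher in 4 of 4 hearts; adjusted p = 0.245 with an estimated correlation; fry 0.0395), and its call ended with dim genes left out (adjusted p = 0.0557). Among 13 endothelial markers 1 rose and 0 fell, also adjusted over the list alone: the transcription factor gene Erg, by 1.77 ± 0.25 in 4 of 4 hearts (adjusted p = 0.0277). Among 14 epicardial and mesothelial markers 1 rose and 0 fell, or 1 and 1 adjusted over the list alone: Aldh1a2, which makes retinoic acid, by 1.79 ± 0.35 in 4 of 4 hearts (adjusted p = 0.0480; 0.104 with no replicate block, and 0.0505 to 0.0620 with 4 other alternatives on all 4 hearts). The cardiomyocyte, endothelial, pericyte and epicardial lists did not shift in camera or fry, with mean differences of 0.01, 0.17, -0.24 and -0.42 and camera adjusted p of 0.803, 0.312, 0.312 and 0.307. The epicardial list passed without the p-MyoFb array of heart D (adjusted p = 0.0339) or the non-p-MyoFb array of heart A (0.0223).

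In this comparison 104 genes were higher and 147 lower, or 1.38% of those tested (limma, adjusted p under 0.05), and 3029 had an unadjusted p under 0.05. Of the called genes 29 and 69 differed at least 2-fold, and all 251 had the same sign in all 4 hearts. Of the 29 lists, 12 shifted in camera and 6 in fry, and 0 shifted in camera with an estimated correlation, where 5 had an unadjusted p under 0.05. Each of the 30 calls named by the rule ended without heart D, where the adjusted p ran from 0.0502 (Sema7a) to 0.25 (Kcnd3). It was 0.117 for Cd34, 0.211 for Mki67, 0.198 for Rrm2, 0.220 for Cdkn2b and 0.233 for Nox4. With the leukocyte list mean as a covariate, added after seeing the data, 0 genes were higher and 0 lower in limma (407 and 646 at an unadjusted p under 0.05). The median rise of the called genes then went from 0.71 to 0.54, their median fall from -0.98 to -0.91 and their median standard error from 0.135 to 0.212, so calls ended mainly because the error grew. With no replicate block the higher genes numbered 59.

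The counts of this comparison changed strongly when single hearts or arrays were left out, which also leaves fewer residual degrees of freedom. Higher and lower genes numbered 0 and 0 in limma without heart C (934 and 1062 at an unadjusted p under 0.05) or heart D (944 and 1114), and 13 and 7 without heart A. Without the p-MyoFb array of heart D or the non-p-MyoFb array of heart C they were also 0 and 0 in limma (1014 and 1140, and 1163 and 1292, at an unadjusted p under 0.05). They were 3 and 0 without the non-p-MyoFb array of heart D (981 and 1229 at an unadjusted p under 0.05), 9 and 9 without the p-MyoFb array of heart A and 12 and 1 without its non-p-MyoFb array. Without the p-MyoFb array of heart C they were 16 and 34, and without an Fb array 158 and 227 (heart A), 51 and 80 (heart B) or 22 and 28 (heart C). Without the non-p-MyoFb array of heart B 178 genes were higher.

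The comparison of non-p-MyoFb with Fb set the ends of the series against each other. Of 30 listed matrix genes 17 were higher and 2 lower in non-p-MyoFb than in Fb, and all 27 mitosis genes were lower. Col11a1 rose by 4.60 ± 0.19 (24.2-fold), Cd34 by 4.47 ± 0.39, Gldn by 4.32 ± 0.27, Postn by 4.14 ± 0.17, Pmepa1 by 4.08 ± 0.15 and Fibin by 4.01 ± 0.35, all in 4 of 4 hearts. Tspan8 fell by 5.39 ± 0.50, Upk3b fell by 5.24 ± 0.47 and Efemp1, a fibulin, fell by 5.14 ± 0.41, all in 4 of 4 hearts. Tspan8 stood at 5.44 to 5.88 in non-p-MyoFb, near the leukocyte markers Ms4a1 (mean 5.53) and Ptprc (5.99). Sgo2 read 4.09 to 5.36 on the same arrays, so whether background limits the fall of Tspan8 cannot be told from these levels. The adhesion receptor gene Adgrd1 fell by 4.78 ± 0.32, Lrrn4 fell by 4.72 ± 0.68 and Pla2g2a fell by 4.63 ± 0.28, also in 4 of 4 hearts. Among these 12 genes the adjusted p ran from 6.25e-06 (Col11a1, Postn and Pmepa1) to 0.00129 (Lrrn4) in limma.

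All 27 mitosis genes fell, also adjusted over the list alone, and the list mean differed by -2.58, lower in 4 of 4 hearts (adjusted p = 2.88e-20; adjusted p = 0.315 with an estimated correlation). Of 26 DNA replication genes, 25 fell and 0 rose by both counts, with a mean of -1.29, lower in 4 of 4 hearts (adjusted p = 1.58e-16; adjusted p = 0.315 with an estimated correlation). Mki67 fell by 4.02 ± 0.39 (adjusted p = 1.82e-04) and Rrm2 fell by 3.86 ± 0.41 (adjusted p = 2.65e-04), each in 4 of 4 hearts. Of 21 CDK inhibitors and senescence genes, 8 rose and 4 fell, or 9 and 5 adjusted over the list alone. Cdkn2b rose by 2.25 ± 0.20, while Cdkn2c, another CDK4 and CDK6 inhibitor, fell by 1.96 ± 0.21 and Lmnb1, lamin B1, fell by 1.91 ± 0.24, each in 4 of 4 hearts. The senescence list did not shift in camera (mean 0.17, adjusted p = 0.295, higher in 4 of 4 hearts) or fry (0.121).

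Of 30 collagens and matrix proteins, 17 rose and 2 fell, or 20 and 2 adjusted over the list alone. The list rose (mean 1.00, adjusted p = 2.16e-07, higher in 4 of 4 hearts; adjusted p = 0.276 with an estimated correlation). Of 19 genes of collagen processing, 9 rose and 1 fell, or 10 and 1 adjusted over the list alone, and that list rose (mean 0.48, adjusted p = 5.95e-04, higher in 4 of 4 hearts; adjusted p = 0.276 with an estimated correlation). P4ha2, a subunit of prolyl hydroxylase, fell by 1.40 ± 0.10 in 4 of 4 hearts (adjusted p = 4.73e-05). Of 26 genes of the TGF-β list, 16 rose and 7 fell, also adjusted over the list alone, with Nox4 up by 3.91 ± 0.27 and Tgfbi at -3.04 ± 0.30. The TGF-β list rose (mean 0.49, adjusted p = 0.0157, higher in 4 of 4 hearts; adjusted p = 0.351 with an estimated correlation). Of 27 contractile genes, 8 rose and 2 fell, or 11 and 3 adjusted over the list alone, and the list rose (mean 0.40, adjusted p = 0.0366, higher in 4 of 4 hearts; adjusted p = 0.478 with an estimated correlation). The contractile call ended without heart B (adjusted p = 0.108), its Fb (0.0539) or non-p-MyoFb array (0.117), or the non-p-MyoFb array of heart C (0.0567) or D (0.0508), and with array quality weights (0.0587). With only the 8 arrays of the 2 groups the calls of Tagln, Col1a1 and Col3a1 ended (adjusted p = 0.0753, 0.0563 and 0.0732). Tagln rose by 1.65 ± 0.45 (adjusted p = 0.0284), a call that ended without heart B (0.103) or C (0.0992), the Fb arrays of hearts B (0.0615) and C (0.0550) or the non-p-MyoFb arrays of hearts B (0.0710), C (0.0658) and D (0.103). Col1a1 rose by 0.45 ± 0.10 (adjusted p = 0.0131), a call that ended without heart B (0.0643), C (0.0958) or D (0.0667) or the Fb array of heart C (0.0519). Col3a1 rose by 0.59 ± 0.16 (adjusted p = 0.0242), a call that ended without heart C (0.128), the non-p-MyoFb array of heart B (0.0752) or C (0.0770) or the Fb array of heart C (0.0710). These 3 genes were higher in 4 of 4 hearts, and Fn1 differed by 0.05 ± 0.06 (adjusted p = 0.589, higher in 3 of 4 hearts).

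Of 26 resting fibroblast genes, 6 rose and 10 fell, or 7 and 13 adjusted over the list alone. The list fell (mean -0.57, adjusted p = 0.0154, lower in 4 of 4 hearts; adjusted p = 0.351 with an estimated correlation), though its member Cd34 rose; Fmod fell by 4.57 ± 0.43. Of 27 interferon response genes, 11 fell and 1 rose, or 12 and 1 adjusted over the list alone, and the list fell (mean -0.40, adjusted p = 6.92e-05, lower in 4 of 4 hearts; adjusted p = 0.276 with an estimated correlation). Of 16 complement genes, 6 fell and 3 rose, or 7 and 3 adjusted over the list alone. The complement list fell (mean -0.86, adjusted p = 0.0157, lower in 4 of 4 hearts; adjusted p = 0.276 with an estimated correlation), a call that ended with no replicate block (adjusted p = 0.0638) or heart as a random effect (0.0512). The members that rose were C1qa, C1qb and C1qc, which the leukocyte list holds too; C1qa and C1qc were named after their values were seen.

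Of 14 epicardial and mesothelial markers, 9 fell and 0 rose, or 11 and 1 both adjusted over the list alone and at an unadjusted p under 0.05 in limma. The list fell (mean -2.05, adjusted p = 7.50e-06, lower in 4 of 4 hearts; adjusted p = 0.351 with an estimated correlation). Of 19 leukocyte markers, 8 rose and 0 fell, or 9 and 0 by the same counts. Lyz2, the lysozyme of macrophages, rose by 2.96 ± 0.38 (adjusted p = 7.51e-04) and Tyrobp, a signalling adaptor, by 1.16 ± 0.18 (adjusted p = 0.00176), each in 4 of 4 hearts. The leukocyte list rose (mean 0.52, adjusted p = 0.00294, higher in 4 of 4 hearts; adjusted p = 0.351 with an estimated correlation). The cardiomyocyte, endothelial, pericyte and Schwann cell lists did not shift in camera, with mean differences of -0.10, 0.26, 0.29 and 0.14 and adjusted p of 0.894, 0.207, 0.321 and 0.389. Fry called the endothelial list (adjusted p = 0.00206) and the pericyte list (0.0406), and the pericyte list passed in camera without heart A (adjusted p = 0.0415).

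Between these ends 2137 genes were higher and 2176 lower, or 23.7% of those tested (limma, adjusted p under 0.05). Of these, 369 and 602 differed at least 2-fold, and 4164 of the 4313 had the same sign in all 4 hearts. Of the 29 lists, 12 shifted in camera and 20 in fry, and 0 shifted in camera with an estimated correlation, where 5 had an unadjusted p under 0.05. Higher and lower genes numbered 1045 and 1147 without heart C and 1238 and 1379 without heart D, and 1412 were higher without the Fb array of heart C. With a list mean as a covariate, added after seeing the data, they numbered 136 and 161 (epicardial and mesothelial), 70 and 64 (leukocyte) or 38 and 41 (mitosis). The median standard error of the called genes went from 0.102 to 0.217, 0.209 and 0.268 with these covariates, their median rise from 0.46 to 0.37, 0.42 and 0.44, and their median fall from -0.60 to -0.45, -0.53 and -0.46.

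The last comparison asked whether the step from Fb to p-MyoFb and the step from p-MyoFb to non-p-MyoFb differed, counted with their sign, so that a gene moving opposite ways can pass with steps of similar size. All 82 genes past this threshold had passed in the first step, and 9 of them also passed in the second, 8 in the opposite direction. Npr3 (probe set 17745928), the clearance receptor of natriuretic peptides, stood at 12.36 ± 0.40 in Fb, 9.36 ± 0.12 in p-MyoFb and 9.85 ± 0.29 in non-p-MyoFb (SD, n = 4). Its second step minus its first was 3.51 ± 0.22 (adjusted p = 0.00111, positive in 4 of 4 hearts). For Postn that difference was -2.99 ± 0.30 (adjusted p = 0.00860) and for Pmepa1 -2.97 ± 0.27 (adjusted p = 0.00676), negative in 4 of 4 hearts. In non-p-MyoFb Postn read 13.53 to 13.72 and Pmepa1 13.10 to 13.41, a range in which arrays compress differences. Whether this made their second steps smaller cannot be told from these values. The steps differed for 0.451% of genes (limma, adjusted p under 0.05), with 32 positive and 50 negative differences, and 2733 genes had an unadjusted p under 0.05.

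Of the 10 genes named by the rule for this comparison, Npr3 kept its call in every fit that left out a heart or an array, and 9 did not. The call of Postn ended without heart B (adjusted p = 0.0569) or C (0.0848) or the p-MyoFb array of heart D (0.0734), and that of Pmepa1 without heart B (0.0567), C (0.0848) or D (0.0694) or the same array (0.0694). The number of genes was 11, 3 and 3 without heart B, C or D. Without the p-MyoFb array of heart A, B, C or D it was 9, 23, 13 or 2, and without the Fb array of heart A, B or C 385, 37 or 43. Without the non-p-MyoFb array of heart B, C or D it was 155, 27 or 22, and with no replicate block 39.

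A total of 102 genes passed in both steps, and 85 of them moved the same way, 48 up and 37 down. The steps compare separate cultures in order of the groups, and no culture was followed over time. Fibin rose by 2.14 and then 1.87, Cdkn2b by 0.83 (3 of 4 hearts) and then 1.42, and Adgrd1 fell by 3.03 and then by 1.75. Id1, a target of BMP signalling, fell by 0.85 and then by 0.97, and Stmn1, a regulator of microtubules, fell by 1.21 and then by 2.26. Another 17 went opposite ways, 11 up and then down, such as Col15a1 (0.85 and then -1.27) and Myc (0.62 and then -0.67), and 6 down and then up, such as Rora (-0.55 and then 0.49). Stmn1, Myc and Rora were named after their values were seen.

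**Figure D3:**
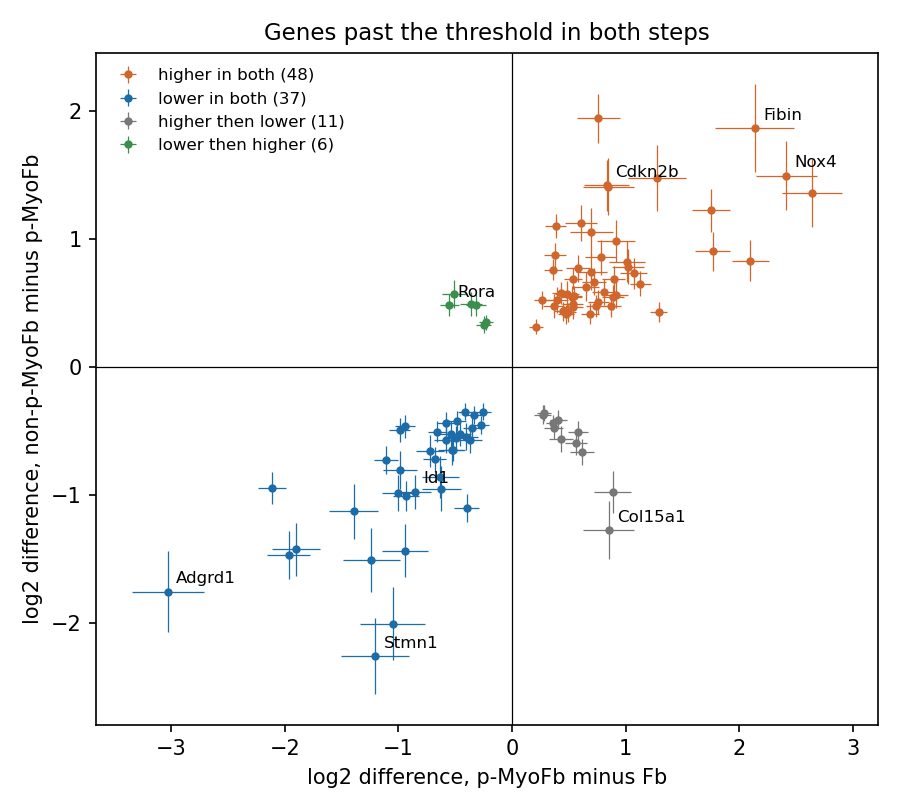
Log2 difference of the second step (non-p-MyoFb minus p-MyoFb, vertical axis) against that of the first (p-MyoFb minus Fb, horizontal axis) for the 102 genes past the threshold in both, with bars of 1 standard error. Of these, 48 lie in the upper right, 37 in the lower left and 17 in the other quadrants.

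Both steps share the p-MyoFb arrays with opposite sign, so error alone pushes genes in opposite directions. Independent lists of the same sizes would share 15.7 genes with the same direction and 16.1 with opposite ones. In 100 simulated sets with no effect limma gave a mean of 0 and 0 such genes, and the steps correlated at -0.50 across genes. Sets with no effect give few calls in either step, so these counts do not show how many genes would be shared where genes change. The measured correlation across genes was 0.26, and 0.22 to 0.32 when the steps came from different hearts in the 6 possible splits; genes are not independent replicates. With the first step from hearts B and C, 80 genes passed in both steps the same way and 4 opposite ways. In the other splits 0 or 1 passed the same way and 0 opposite ways, where 0 to 43 genes passed in the second step. The number with the same direction was 0 without heart C or D, the p-MyoFb array of heart D or the non-p-MyoFb array of heart C, where limma also called 0 genes in the second step. It was 12 and 39 without heart A or B, 10, 52 and 7 without the p-MyoFb array of heart A, B or C, and 148, 34 and 16 without the Fb array of heart A, B or C. Without the non-p-MyoFb array of heart A or D it was 8 and 2, and with no replicate block 51.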

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

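The tests on heart A, on the share of mesothelial cells, on fewer fibroblasts and on the correlation of markers were chosen after the results were seen, and so were the covariates.

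The mitosis genes differed between hearts in p-MyoFb against Fb, with a list mean of 0.40 in heart A and -0.27, -1.73 and -1.76 in hearts D, B and C. A swap of the p-MyoFb and Fb arrays of heart A would reverse most genes there, while 81.9% of the 2334 genes called from the other 3 hearts had the same direction in heart A, which argues against it. Mixing of Fb RNA into the p-MyoFb array of heart A would move its mitosis genes toward Fb and not above it. They averaged 9.87 there against 9.47 in Fb of that heart. A large share of Fb RNA was taken to leave the other genes at 0.25 or less of the change elsewhere. The median ratio was 0.51 in heart A (bootstrap interval over genes 0.488 to 0.538), against 0.82, 0.86 and 1.19 in hearts B, C and D. That argues only against a share as large as this. A smaller share could leave such a ratio, and the interval does not cover differences between hearts. The ratio therefore cannot decide on mixing. The reverse, p-MyoFb RNA in the Fb array of heart A, was not tested. That array lay at 22.8 on the first component, against 39.4 to 51.7 for the other Fb arrays. A difference between the hearts in how fast the cells divided stays open and was not tested.

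Epicardial and mesothelial markers were higher in Fb, with list means of 9.56 ± 1.09 in Fb, 7.92 ± 0.62 in p-MyoFb and 7.51 ± 0.14 in non-p-MyoFb (SD, n = 4), and a candidate source is mesothelial cells in the Fb cultures. The markers correlated within groups more than 100% of 10000 random lists did (mean r 0.54 against a median of -0.006). Regulation together within cells present in every group, fibroblasts or others, would give this as well. Of 14 markers 0 are in another list, and 11, 7 and 3 stood above the median gene in Fb, p-MyoFb and non-p-MyoFb. Upk3b averaged 12.25 in Fb, and Msln stood at 8.98, 11.62, 13.03 and 13.39 there in hearts A to D. In p-MyoFb Msln stood at 7.29, 8.80, 11.83 and 9.10 in hearts A to D, so the signal was not confined to Fb. The labels name a second passage and no sort or gate. Whether such cells account for the higher genes in p-MyoFb cannot be told apart: the rise in heart A, B, C or D was 0.51, 0.84, 0.90 or 1.20 of that in the other hearts and the fall of the markers 0.505, 0.806, 0.740 or 2.42. In hearts A, B and C the rise lay above the ratio of the markers but within its bootstrap interval over markers (0.320 to 0.721, 0.524 to 1.02 and 0.555 to 0.997). In heart D the rise lay below that interval (2.11 to 2.98). The interval of the rise over genes was 0.485 to 0.547, 0.803 to 0.882, 0.861 to 0.946 and 1.14 to 1.25 in hearts A to D. It held the ratio of the markers in hearts A and B, lay above it in heart C and below it in heart D. Fewer fibroblasts in Fb as the whole cause of the rises of at least 2-fold would lift resting fibroblast genes by at least 1. Their median difference was -0.0452 (median absolute deviation 0.588), which argues against it unless those genes also fell for another reason. More mesothelial cells in Fb would mean fewer fibroblasts there, so these values bear on them in the same way. They do not bear on a part of the rises.

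Leukocyte markers were higher in non-p-MyoFb, with list means of 6.61, 6.74 and 7.13 along the series, and a candidate source is leukocytes in those cultures. The markers correlated within groups more than 100% of 10000 random lists did (mean r 0.29 against a median of 0.022), and regulation together would give this as well. Of 19 markers 3 are in another list, and 1, 2 and 6 stood above the median gene along the series. In non-p-MyoFb Lyz2 averaged 9.67, Tyrobp 8.28, Cd68 7.61 and Ptprc 5.99, against 6.72, 7.12, 7.16 and 5.70 in Fb. Other members hardly differed, such as Cd3e, Cd2, Cd79b and Ms4a1 at 5.25, 5.38, 7.18 and 5.53 in non-p-MyoFb against 5.18, 5.35, 7.21 and 5.52 in Fb. Expression of the higher genes by the fibroblasts under TGF-β1 stays open and was not tested.

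Single arrays lay far from the other 3 of their group for 19 of 402 gene values and 4 of 87 list means, where chance flags about 1 in 20, or 20.1 and 4.35. Of these 23 values, 14 were of heart A, 2 of heart B, 2 of heart C and 5 of heart D.

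In Fb, heart A had Mcam at 10.12 (others 7.29 to 7.57), Il1rl2 at 10.01 (7.91 to 8.08), Nox4 at 7.03 (6.24 to 6.29), Ndrg1 at 9.72 (10.69 to 10.84) and Adgrd1 at 11.47 (12.95 to 13.04). Heart D had Lif at 8.52 in Fb (others 9.17 to 9.29) and Spp1 at 7.50 (7.08 to 7.13), and heart B a mean of the cytokine and chemokine list of 8.83 (8.40 to 8.43). In p-MyoFb, heart A had Myl9 at 12.54 (others 11.97 to 12.04), Mgp at 11.38 (12.87 to 13.17) and a mean of the adipogenic list of 7.76 (7.90 to 7.93), and heart B had Pla2g2a at 9.42 (7.54 to 7.81). In non-p-MyoFb, heart A had Col3a1 at 12.99 (others 13.26 to 13.30), P3h2 at 10.48 (8.45 to 8.75), Vcl at 12.28 (12.06 to 12.09), Creb3l1 at 10.13 (10.37 to 10.38) and Il1rl2 at 10.48 (9.55 to 9.70). The mean of its collagen list was 11.24 (11.73 to 11.81). Heart C had Tspan8 at 5.44 in non-p-MyoFb (others 5.84 to 5.88) and C6 at 7.00 (6.69 to 6.72). Heart D had Igfbp4 at 10.43 (8.85 to 9.08), Kcnmb1 at 7.49 (8.66 to 8.67) and a mean of the Wnt list of 8.75 (8.64 to 8.66).

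A signal also appeared in the 11145 probe sets without a single gene symbol, which the comparisons of genes did not use. Of these, 395 passed for p-MyoFb against Fb (200 higher and 195 lower), 20 for non-p-MyoFb against p-MyoFb (7 and 13) and 1014 for non-p-MyoFb against Fb (599 and 415). These are 3.54%, 0.179% and 9.10% of them, adjusted over all probe sets, against 12.7%, 1.38% and 23.7% of the genes tested.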

How the results depend on the processing

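The covariates were added after seeing the data; the other alternatives were not.

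Of 231 results of named genes 203 were called, and 109 of these kept call and sign under every alternative run on named genes, leave-outs included. None of the 231 reversed there, where a reversal is a change of sign in a result called in the reported or the alternative fit. Changes of sign in results called in neither fit occurred 5 times. The covariates, the 1.5-fold and 0.01 thresholds and the test of all probe sets were applied to the counts of genes and not to these 231 results. Leaving out 1 heart or array ended 33 of 74 calls for p-MyoFb against Fb, 30 of 30 for non-p-MyoFb against p-MyoFb, 16 of 89 for non-p-MyoFb against Fb and 9 of 10 for the difference of the steps. Of 38 list calls 23 held under every setting with the preset correlation, 0 of 29 lists per comparison shifted in camera with an estimated correlation (4, 5 and 5 at an unadjusted p under 0.05), and fry called 12, 6 and 20. None of the list results reversed in that sense, and lists called in neither fit changed direction 115 times.

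Without a heart, higher and lower genes ranged from 357 to 1171 and 379 to 1163 for p-MyoFb against Fb, from 0 to 97 and 0 to 104 in limma for non-p-MyoFb against p-MyoFb, and from 1045 to 1885 and 1147 to 1925 for non-p-MyoFb against Fb. Without an array the ranges were 539 to 1302 and 497 to 1209, 0 to 178 and 0 to 227, and 1412 to 2078 and 1494 to 2119. Where limma gave 0, the lowest counts at an unadjusted p under 0.05 were 934 and 1062. The steps differed for 3 to 121 genes without a heart and 2 to 385 without an array, and 0 to 39 and 0 to 148 moved the same way in both. Shifted lists numbered 12 to 15, 10 to 12 and 10 to 18 without a heart and 12 to 16, 10 to 13 and 10 to 15 without an array. Fewer arrays leave fewer residual degrees of freedom. The rise without the Fb array of heart A has a cause that was not tested.

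With no replicate block, 59 genes were higher for non-p-MyoFb against p-MyoFb, 39 differed between the steps and 51 moved the same way in both; leaving out the block changed no other count by more than 1.5 times. It ended 40 of the 203 gene calls and added 4. With only the 8 arrays of 2 groups, higher and lower genes numbered 795 and 716 for p-MyoFb against Fb, and 1415 were higher for non-p-MyoFb against Fb. The difference of the steps needs all 3 groups and had no value there. With array quality weights the counts were 2063 and 1925 for p-MyoFb against Fb, 261 and 337 for non-p-MyoFb against p-MyoFb, 629 for the steps and 257 the same way in both. The cause of these changes was not tested.

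Testing all probe sets gave 48 and 76 for non-p-MyoFb against p-MyoFb and 44 the same way in both steps, with more tests adjusted for. A further threshold of 1.5-fold left 475 and 568 for p-MyoFb against Fb, 61 higher for non-p-MyoFb against p-MyoFb, 798 and 1104 for non-p-MyoFb against Fb and 41 the same way. An adjusted p under 0.01 left 423 and 396, 5 and 1, and 1065 and 1189 in these comparisons, 12 for the steps and 0 the same way in both. Leaving out dim genes kept 11202 and gave 169 for the steps, with fewer tests adjusted for. Heart as a random effect, a trended and robust prior, quantile normalization, equal array medians and the mean of probe sets changed no count by more than 1.5 times.

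With the mean of the epicardial and mesothelial list as a covariate the counts were 49 and 36 for p-MyoFb against Fb, 136 and 161 for non-p-MyoFb against Fb, 2 for the steps and 14 the same way in both. With the leukocyte list mean, 667 were lower for p-MyoFb against Fb, 0 and 0 passed in limma for non-p-MyoFb against p-MyoFb (407 and 646 at an unadjusted p under 0.05), 70 and 64 for non-p-MyoFb against Fb, 7 for the steps and 0 for both. With the mitosis list mean the counts were 496 and 528, 1 and 0 in limma (551 and 529 at an unadjusted p under 0.05), 38 and 41, 24 and 1. Group and heart held 85.6%, 82.8% and 87.9% of the variance of these means, so a covariate shares much of the group difference. With the mitosis mean the median fall of the called genes for non-p-MyoFb against p-MyoFb went from -0.98 to -0.37 and their median standard error from 0.135 to 0.203, so differences shrank and the error grew. Postn went from 3.56 ± 0.17 to 3.28 ± 0.32 for p-MyoFb against Fb with the first covariate and passed (adjusted p = 0.0150). Tspan8 went from -4.32 ± 0.50 to -2.05 ± 0.39, where the difference itself shrank (adjusted p = 0.0761). Cd34 went from 3.99 ± 0.39 to 3.21 ± 0.62 for non-p-MyoFb against p-MyoFb with the leukocyte mean (adjusted p = 0.703), mainly because the error grew.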

Other observations

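The tests on other splits of the samples were chosen before the results were seen.

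Pathways outside the matrix moved in single genes from Fb to p-MyoFb. Of 23 BMP pathway and ID genes, 5 rose and 5 fell (6 and 8 adjusted over the list alone). Among them Gdf6, a BMP ligand, rose by 2.02 ± 0.29 (adjusted p = 0.00287), the activin-binding Fstl3 rose by 1.84 ± 0.22 (adjusted p = 0.00130) and Smad9 fell by 1.81 ± 0.20 (adjusted p = 9.59e-04). The secreted Wnt modulator Sfrp2 fell by 3.11 ± 0.50 (adjusted p = 0.00480), while the receptor gene Fzd8 rose by 1.95 ± 0.24 (adjusted p = 0.00128). Egfr, the EGF receptor, fell by 1.81 ± 0.10 (adjusted p = 3.78e-05), Igfbp4 fell by 2.76 ± 0.28 (adjusted p = 6.29e-04) and the cytokine gene Lif rose by 1.60 ± 0.26 (adjusted p = 0.00533). Vcam1, an adhesion molecule, fell by 1.99 ± 0.30 (adjusted p = 0.00348), and its call ended with no replicate block (adjusted p = 0.189) or heart as a random effect (0.101). Each of these 9 genes moved alike in 4 of 4 hearts.

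The BMP, cytokine, Wnt and growth factor lists did not shift for p-MyoFb against Fb (camera adjusted p = 0.236, 0.0564, 0.982 and 0.982), nor did the resting fibroblast list (0.0855), the CDK inhibitor list (0.476), the protease list (0.611) or the YAP and SRF list (0.576). The resting fibroblast list passed without heart B (0.0436), its Fb array (0.0413) or that of heart C (0.0466). The cytokine list passed without heart A (0.0217) or D (0.0399), either Fb array of these hearts (0.0209 and 0.0372), the Fb array of heart C, the p-MyoFb array of heart D (0.0462) or the non-p-MyoFb array of heart A (0.0429) or B (0.0463), with no replicate block (0.0453), heart as a random effect (0.0459), only the 8 arrays (0.0459), array quality weights (0.0391) and quantile normalization (0.0408). The cartilage and bone, glycolysis and ion channel lists did not either (0.236, 0.236 and 0.549). Of 20 adipogenic genes, 4 fell and 0 rose, also adjusted over the list alone, with Zfp423 at -1.05 ± 0.12 (adjusted p = 0.00113, lower in 4 of 4 hearts). The adipogenic list fell (mean -0.20, adjusted p = 0.0450, lower in 4 of 4 hearts; adjusted p = 0.340 with an estimated correlation), a call that ended without heart A (adjusted p = 0.294) or either its p-MyoFb or its Fb array (0.218 each), with array quality weights (0.141) and with dim genes left out (0.0786). With no replicate block its adjusted p lay just above 0.05. Of 18 cholesterol synthesis genes, 1 fell and 0 rose, also adjusted over the list alone, and this was Stard4, at -0.88 ± 0.16 (adjusted p = 0.00768, lower in 4 of 4 hearts; 0.0759 and 0.0665 without heart C or D). The cholesterol list fell (mean -0.25, adjusted p = 0.0143, lower in 4 of 4 hearts; adjusted p = 0.698 with an estimated correlation), not in fry (0.409). That call ended without heart A (adjusted p = 0.0826) or C (0.0526), the p-MyoFb array of heart A (0.218) or C (0.102) or the Fb array of heart B (0.181), and with dim genes left out (0.0600).

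From p-MyoFb to non-p-MyoFb, Id1 fell by 0.97 ± 0.14 (adjusted p = 0.0267; 0.0510 with no replicate block), and the BMP list did not shift in camera (mean -0.13, adjusted p = 0.0746, lower in 4 of 4 hearts) and fell in fry (0.0343). Adamts12, a metalloprotease, rose by 1.31 ± 0.17 (adjusted p = 0.0267; 0.0507 with no replicate block), Wnt11 by 0.59 ± 0.09 (adjusted p = 0.0343) and Pdgfa by 0.54 ± 0.10 (adjusted p = 0.0407). Fos fell by 0.89 ± 0.15 (adjusted p = 0.0407; 0.121 with no replicate block, 0.0599 with heart as a random effect and 0.0603 with only the 8 arrays) and S100a4 fell by 1.44 ± 0.28 (adjusted p = 0.0463; 0.0771 with only the 8 arrays and 0.0609 with a trended and robust prior). Each of these 6 genes moved alike in 4 of 4 hearts, and without heart D the adjusted p ran from 0.198 (Adamts12) to 0.248 (S100a4). The protease list rose (mean 0.22, adjusted p = 0.0103, higher in 4 of 4 hearts; adjusted p = 0.462 with an estimated correlation) and not in fry (0.17), a call that ended without the p-MyoFb array of heart A (adjusted p = 0.0789). The Wnt list rose (mean 0.09, adjusted p = 0.0191, higher in 3 of 4 hearts; adjusted p = 0.245 with an estimated correlation), a call that ended without heart B (adjusted p = 0.10) or its p-MyoFb (0.0909) or non-p-MyoFb array (0.0622). The YAP and SRF list fell (mean -0.19, adjusted p = 0.00467, lower in 4 of 4 hearts; adjusted p = 0.245 with an estimated correlation).

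Collagen processing genes rose as a list there (mean 0.18, adjusted p = 0.0197, higher in 4 of 4 hearts; adjusted p = 0.245 with an estimated correlation), though the 1 called member of 19, P4ha2, fell by 0.72 ± 0.10 (adjusted p = 0.0267, lower in 4 of 4 hearts; 0.215 without heart D). The list call ended in fry (adjusted p = 0.0778) and without heart C (0.0537), its non-p-MyoFb array (0.0850) or the p-MyoFb array of heart D (0.0604). Of 26 resting fibroblast genes, 1 rose and 2 fell, or 2 and 6 adjusted over the list alone. The list fell (mean -0.16, adjusted p = 0.0191, lower in 4 of 4 hearts; adjusted p = 0.462 with an estimated correlation) and not in fry (0.219). The call ended without heart B (adjusted p = 0.12) or its p-MyoFb (0.133) or non-p-MyoFb array (0.0543) and with dim genes left out (0.0602).

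Between non-p-MyoFb and Fb, Sfrp2 fell by 4.03 ± 0.50 (adjusted p = 5.86e-04), Fzd8 rose by 2.56 ± 0.24 (adjusted p = 1.40e-04), Spp1, osteopontin, rose by 2.87 ± 0.49 (adjusted p = 0.00322) and Fap, fibroblast activation protein, rose by 2.36 ± 0.21 (adjusted p = 1.24e-04), all in 4 of 4 hearts. Ccn2, a target of TGF-β and YAP, rose by 1.08 ± 0.16 (adjusted p = 0.00173) in 4 of 4 hearts. Gja1, connexin 43, fell by 2.60 ± 0.55 in 4 of 4 hearts (adjusted p = 0.00873), a call that ended without heart C (adjusted p = 0.0707) or D (0.0647). Of 27 genes of the unfolded protein response and secretory pathway, 10 rose and 2 fell, or 13 and 2 adjusted over the list alone. That list rose (mean 0.21, adjusted p = 0.0366, higher in 4 of 4 hearts; adjusted p = 0.351 with an estimated correlation), a call that ended without heart B (adjusted p = 0.0728) or C (0.0521), the Fb array of heart B (0.0701) or C (0.0563) or the non-p-MyoFb array of heart B (0.0521) or D (0.0508).

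Other splits of the 8 arrays of 2 groups into 4 and 4, without the heart block, asked whether any grouping gives as many genes. In that fit, which ignores the pairing by heart, 1 of 35 splits, the real one, gave as many genes in each comparison. This argues against chance in the unpaired fit only, since the arrays are paired. The real numbers were 1081, 127 and 3123 for p-MyoFb against Fb, non-p-MyoFb against p-MyoFb and non-p-MyoFb against Fb, and the highest others 8, 1 and 1. Splits that part all 4 pairs, with the heart block, number 8, too few for a share under 0.05. There the real split gave 1511, 279 and 2964 genes and the highest other 0 in limma, so 1 of 8 splits was as large. Within hearts chance was therefore not excluded for these numbers. For the number of shifted lists 1 of 35 splits was as large for p-MyoFb against Fb (15 lists, highest other 11). This argues against chance only for camera at the preset correlation without the heart block. With the block and an estimated correlation 0 of 29 lists shifted in that comparison (4 at an unadjusted p under 0.05, and 12 in fry). With 4 of 35 (11 lists, highest other 11) and 2 of 35 (15 lists, highest other 16) chance was not excluded for the other 2 comparisons.

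Regrouping the 3 arrays within each heart gave as many genes as the 82 of the difference of the steps in 7 of 100 drawn regroupings, the real one included, so by this test, fixed beforehand, chance was not excluded for the 82 genes. In the other 6 all 4 arrays of Fb or of non-p-MyoFb stood in the middle place, so they carry differences between the real groups, which was looked at after the result was seen. The highest of them gave 3093 genes, which points to a structure of the samples, and the median over all other regroupings was 0 in limma.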
